A study of Mus musculus with 8 samples.

How the data were processed

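Total RNA from mouse livers was sequenced in 8 libraries of paired reads, per the labels' protocols. Reads were trimmed with cutadapt 1.9.1, aligned with HISAT2 2.2.1 to GRCm39 and counted with HTSeq 0.6.1, per the submitters' processing notes, which list these tools and the build. The annotation release, the strand setting and the counting mode are not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty. The deposited table gives a raw read count per gene and library for 56691 genes, per the file headers. It also gives FPKM values (fragments scaled to exon length and library size), per the file headers. The deposited FPKM was checked against the count divided by the exonic length and the library's total count, in the units of FPKM. Over all values, the difference was at most 0.00500, which is the rounding to 2 decimals. Gene symbols and coordinates are those of the table, on GRCm39. Symbols of the gene lists that were absent from the table were looked up as synonyms in a RefSeq table of another build, whose coordinates were not used.

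Groups and replicate numbers came from the sample titles. The labels describe mice but do not state that each library is a separate animal, so p-values measure the spread between these 8 libraries. Library totals ranged from 15885113 to 19850800 counts. The planned test for FPKM alone was limma on log2(FPKM + 0.5). The plan named edgeR's quasi-likelihood test for a table that also held counts, and because counts were present that test was used. Genes were kept by filterByExpr (14533 genes), libraries were scaled by TMM, the model held the group only, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Log2 fold changes are plive-Tet1 over plive-Con, and their SE and 95% intervals come from the quasi-likelihood statistic. Tet1 had too few counts for filterByExpr and was tested by an exact permutation test over the 70 assignments of 4 of the 8 libraries.

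Of 45 gene lists written before the data were examined, 41 had at least 5 tested members. They were tested with camera on log2 CPM (prior count 2) at a preset correlation of 0.01, and beside it with camera at an estimated correlation, fry, and an exact permutation test of the mean standardised value per library. Counts called adjusted over the list alone use the edgeR p-values of the list's members. The genes to be named were also fixed before the data were examined. They were 23 genes of the TET family, of DNA methylation and of the diet model, the 10 smallest p-values in each direction because fewer than 5 genes passed, and the 2 to 4 members of each described list with the smallest p. Some members that this rule names are not reported here. Other members, such as Alas2, were named after their values had been seen. Libraries were compared by principal components and Pearson correlations of log2(FPKM + 0.5) of the tested genes.

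No pair of libraries within a group agreed within sampling noise: chi-square per degree of freedom was between 12.9 and 77.6 over genes with at least 10 counts in a pair. The edgeR test was tested on simulated data with 200 genes seeded with a change, of which 66, 66 and 63 at the 3 fold sizes were among the 14325 tested. There 9 of 127 calls were false. Alternatives covered pseudocounts, filters, scaling, limma settings, library weights, the replicate number as a block and each library left out. DESeq2, limma voom, library totals, robust edgeR, limma on log2(FPKM + 0.5) and a filter of more than 20 counts were added after seeing the data.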

Results

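Liver RNA of wild-type C57BL/6J mice was sequenced in 8 libraries, 4 from mice that had received the control plasmid plive-Con and 4 from mice that had received plive-Tet1. The labels do not state that each library is a separate animal, and a library is called a liver for short. A hydrodynamic injection pushes a large volume into the tail vein so that liver cells take up plasmid. The series title names hepatocyte Tet1 overexpression in a mouse model of metabolic dysfunction-associated steatohepatitis (MASH), and the animals ate a high-fat, choline-deficient, amino acid-defined diet (HFD-CDAA) for 4 weeks from an age of 6 weeks. The mice were killed after a short fast. The libraries held between 15885113 and 19850800 counts assigned to genes, and between 20831 and 21659 genes had at least 1 count in a library. Pearson correlations between libraries, across genes, ranged from 0.976 to 0.992. The first principal component held 29.7% of the variance, and plive-Con 4 lay at its end with a score of 35.5, while the next highest, plive-Con 3, had 9.999 and the lowest, plive-Tet1 1, -17.6. The groups did not separate on it.

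Tet1, which encodes an enzyme that oxidises 5-methylcytosine in DNA, was close to the detection floor in every liver. Its gene (ENSMUSG00000047146, GRCm39 chromosome 10, 62640349 to 62744775, minus strand, 15457 exonic bases) collected 1, 9, 6 and 5 counts in the plive-Con livers and 9, 8, 12 and 5 counts in the plive-Tet1 livers. The mean level was 0.312 ± 0.199 CPM (counts scaled to the library size after TMM; SD, n = 4) with plive-Con and 0.450 ± 0.153 CPM (SD, n = 4) with plive-Tet1. The pooled counts, 34 against 21, gave a ratio of 1.45 with an exact 95% interval from 0.815 to 2.62, which covers counting error only. An exact permutation test of log2(FPKM + 0.5) over the 70 assignments gave a two-sided p of 0.371, where the smallest possible value is 0.0286. A higher level of reads on this gene was therefore not detectable in the livers labelled plive-Tet1. Pooled ratios above 2.62 lay outside the interval of counting error. Tet1 is overlapped by 2 other genes of the table, and the strand setting of the counting is not given in the sources used here. Whether the plasmid's insert has the sequence of the mouse gene is not given in the sources used here. The treatment field of plive-Tet1 replicates 2, 3 and 4 names Tet2, Tet3 and Tet4, whereas their titles and the treatment protocol name Tet1, so grouping followed the titles.

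Tet2 and Tet3, the other members of the family, were expressed at higher levels than Tet1 and did not differ between the groups beyond the spread of the libraries. Tet2 measured 8.06 ± 2.67 CPM with plive-Con and 7.19 ± 0.820 CPM with plive-Tet1 (SD, n = 4 each), and the exact permutation p on the log2 FPKM scale was 0.771. Tet2 stood at 7.10 CPM in plive-Tet1 2, and Tet3 at 31.0 CPM in plive-Tet1 3, the libraries whose treatment field names them. Tet3 measured 28.7 ± 2.21 and 29.9 ± 2.83 CPM (SD, n = 4 each), with an exact permutation p of 0.257. Of the DNA methyltransferases, Dnmt1 had a log2 fold change (plive-Tet1 over plive-Con) of 0.09 ± 0.18 (SE), Dnmt3a of 0.17 ± 0.16 and Dnmt3b of 0.30 ± 0.34. None of the 19 tested members of the list of TET and DNA methylation genes passed the test, over all genes or adjusted over the list alone.

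**Figure D1:**
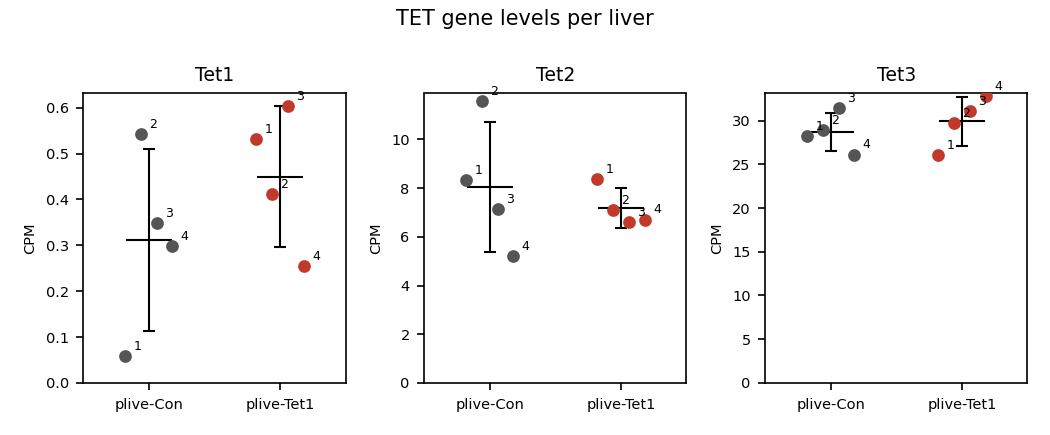
Level of Tet1, Tet2 and Tet3 in each liver, in CPM on a linear axis from 0. Points are single livers with their replicate number, and the bar and whiskers give the group mean and SD (n = 4); Tet1 lay between 0.0579 and 0.604 CPM in all 8 livers.

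The comparison of plive-Tet1 with plive-Con livers asked which genes differ with the Tet1 plasmid on this diet. Cyp4a12a, a fatty acid hydroxylase with male-biased liver expression, measured 78.9 ± 11.4 CPM with plive-Tet1 and 40.6 ± 6.39 CPM with plive-Con (SD, n = 4 each). Ntrk2, a neurotrophin receptor, measured 11.7 ± 1.37 against 3.49 ± 1.87 CPM. Cyp26a1, which degrades retinoic acid, measured 4.96 ± 0.634 against 10.2 ± 1.92 CPM, and the clock gene Per3 measured 8.57 ± 2.71 against 18.99 ± 5.37 CPM. No gene passed the test, however: edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower among 14533 tested at an adjusted p of 0.05. The smallest edgeR adjusted p was 0.271, for Cyp4a12a. An unadjusted p under 0.05 was reached by 591 genes, 277 of them with higher and 314 with lower values, where 727 would be reached by chance. DESeq2, added after the data had been seen, called 5 genes higher and 6 lower. limma voom called 0, with 554 genes at an unadjusted p under 0.05, and limma on log2(FPKM + 0.5) called 0, with 538.

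On GRCm39, Cyp4a12a (ENSMUSG00000066071) lies on chromosome 4 from 115156243 to 115190012 and Ntrk2 (ENSMUSG00000055254) on chromosome 13 from 58954383 to 59281784. Cyp26a1 (ENSMUSG00000024987) lies on chromosome 19 from 37686246 to 37689984 and Per3 (ENSMUSG00000028957) on chromosome 4 from 151088109 to 151129122. The values of the groups did not overlap in 2.28% of the genes, and chance gives 2.86%. Simulated counts were drawn for each gene independently, at the spread edgeR estimated for it in these libraries, with 200 genes seeded with a change. There the edgeR test recovered 96.8% of genes changed 4-fold, 71.2% of those changed 2-fold and 15.2% of those changed 1.5-fold. The Benjamini-Hochberg adjustment is stricter where fewer genes change, so recovery would then be lower than these shares. Correlation between genes and a library standing apart, both seen in the real data, were not simulated, so these shares may not carry over to it.

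Of the 10 genes with higher values and the smallest p, none past the threshold, Cyp4a12a had a log2 fold change of 0.96 ± 0.15 (SE), Ntrk2 of 1.74 ± 0.35 and Chrm3, a muscarinic acetylcholine receptor, of 1.40 ± 0.29. Cyp4a12b, a close copy of Cyp4a12a, had a log2 fold change of 0.97 ± 0.22, and reads shared between the copies leave the split between them uncertain. Golm1, a Golgi membrane protein, had 0.68 ± 0.16, and Ihh, the Indian hedgehog ligand, had 0.90 ± 0.22. The others were Denn2b (0.58), Fam83a (1.02), Gm43305 (1.10) and E030013I19Rik (1.38), the last at only 0.443 CPM with plive-Con and 1.17 CPM with plive-Tet1. Of the 10 genes with lower values, Cyp26a1 had a log2 fold change of -1.04 ± 0.19, Per3 of -1.14 ± 0.25 and Serpina6, which encodes corticosteroid-binding globulin, of -0.60 ± 0.14. Abcg5, a subunit of the biliary sterol transporter, had -0.64 ± 0.15, and Prf1, which encodes perforin, had -1.44 ± 0.34. Prf1 was low in both groups, at 1.43 CPM with plive-Con and 0.523 CPM with plive-Tet1. The alpha-globin genes Hba-a1 and Hba-a2, near-identical copies, had -0.96 ± 0.21 and -1.20 ± 0.29. The remaining genes were Fbf1 (-0.86), Smim4 (-0.92) and Cldn5 (-0.78). The 11 genes called by DESeq2 were all among these 20: Cyp4a12a, Ntrk2, Chrm3, Gm43305 and Cyp4a12b with higher values, and Cyp26a1, Per3, Hba-a1, Fbf1, Serpina6 and Hba-a2 with lower values, with DESeq2 adjusted p from 6.00e-05 to 0.0332.

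**Figure D2:**
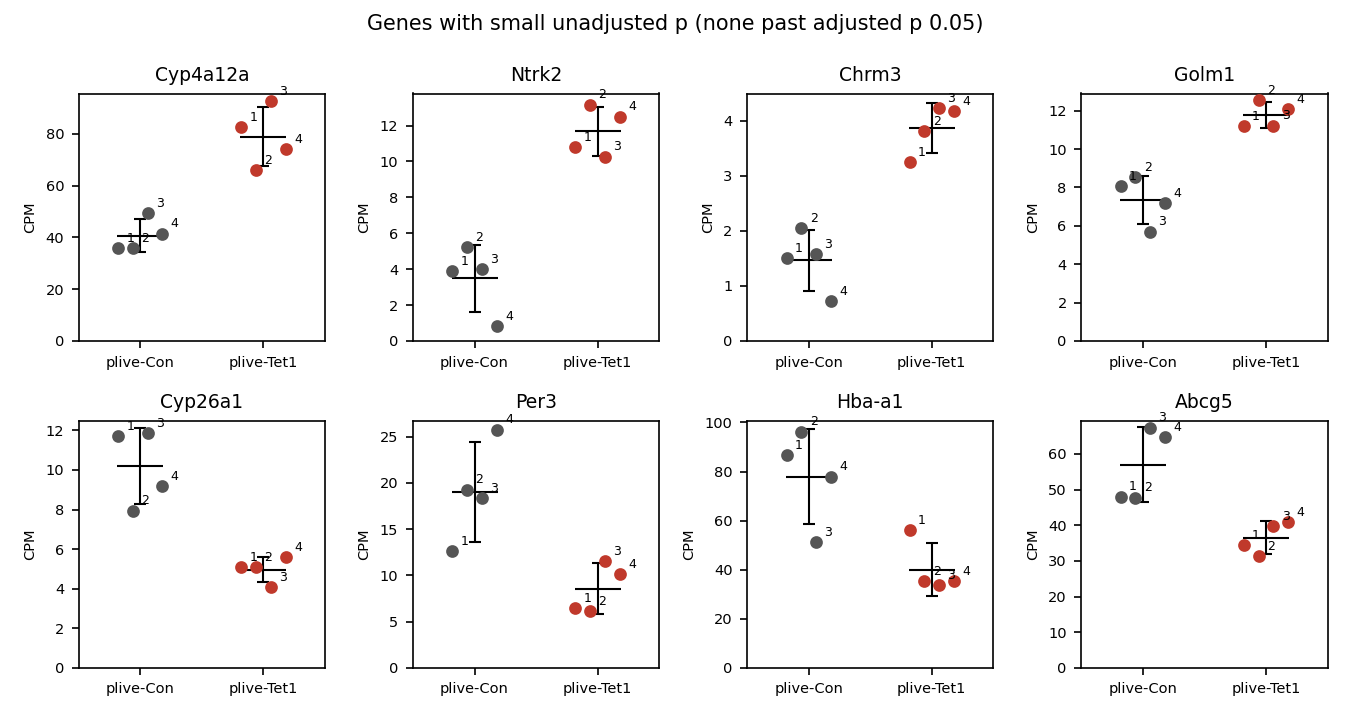
Level in each liver, in CPM on linear axes from 0, of 8 of the 20 genes with the smallest unadjusted p. Points are single livers with their replicate number, and the bar and whiskers give the mean and SD (n = 4); Cyp4a12a lay between 66.0 and 92.6 CPM with plive-Tet1 and between 35.8 and 49.4 CPM with plive-Con, at an edgeR adjusted p of 0.271.

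The readouts of the diet model did not pass the test either. The collagen genes Col1a1 and Col3a1 had log2 fold changes of 0.18 (95% interval -0.34 to 0.70) and 0.34 (-0.14 to 0.81). Acta2, a marker of activated stellate cells, had -0.07 ± 0.37 (SE), a value whose sign differed in the limma fits, and Timp1, an inhibitor of matrix metalloproteinases, had -0.18 ± 0.31. Among inflammatory genes, Tnf had -0.79 ± 0.37, Il1b -0.38 ± 0.28 and Ccl2 0.05 ± 0.30. The macrophage genes Adgre1 and Trem2 had 0.40 ± 0.19 and 0.51 ± 0.20. For lipid metabolism, Fasn had 0.02 ± 0.16, Srebf1 -0.19 ± 0.20, Scd1 0.58 ± 0.38, Ppara 0.12 ± 0.24 and Cpt1a -0.15 ± 0.17. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had -0.04 ± 0.26, Alb, which encodes albumin, -0.14 ± 0.20 and the proliferation marker Mki67 0.40 ± 0.32.

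Gene lists fixed before the data were examined were compared with all other genes by camera at a preset correlation of 0.01. Of 41 lists with at least 5 tested members, 18 passed at an adjusted p of 0.05, 4 towards higher and 14 towards lower values. None of these 18 calls held with an estimated correlation: camera with that setting called 0 lists, with 2 at an unadjusted p under 0.05. fry called 0, with 3 under that value. The exact permutation test of the list mean could hardly call a list after adjustment, since its smallest possible p is 0.0286 before it; the B and plasma cell list and the red cell list were at that value. Ranges of camera's adjusted p for single lists cover the settings that kept the preset correlation. Over all genes tested, 0 members of any list passed the test.

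Markers of lymphoid cells had lower values with plive-Tet1. Of 24 tested T and NK cell markers, 23 had a lower value, 0 rose, 1 fell adjusted over the list alone and 23 did not pass. That gene was Prf1, at a low mean level of 1.43 CPM with plive-Con and 0.523 CPM with plive-Tet1. Klrk1 had a log2 fold change of -0.74 (3.44 and 2.06 CPM) and Cd4 of -0.65 (1.96 and 1.25 CPM). By the mean standardised value of the list, however, plive-Con 3 was the lowest of all 8 livers at -0.933, while the plive-Tet1 livers lay between -0.609 and -0.203 and the other plive-Con livers between 0.667 and 1.07. The list's median was -0.70, with a camera adjusted p of 6.17e-09 and an adjusted p of 0.414 with an estimated correlation. Of 14 B and plasma cell markers, 13 had a lower value and 0 passed adjusted over the list alone. Igkc, the kappa light chain constant region, had -1.44, Jchain -1.73 (-2.45 without plive-Tet1 2) and Cd79a -0.77, with a camera adjusted p of 5.77e-07 and an adjusted p of 0.278 with an estimated correlation. Of 17 dendritic cell markers, 16 had a lower value, Xcr1 with -0.66 and H2-Ab1 with -0.38, and 0 passed adjusted over the list alone. Xcr1 was low in both groups, at 1.40 CPM with plive-Con and 0.889 CPM with plive-Tet1. Here too plive-Con 3, at a mean standardised value of -0.637, lay below plive-Tet1 1, 2 and 3. For this list camera gave an adjusted p of 7.04e-05, and the adjusted p was 0.513 with an estimated correlation. Neutrophil markers, 11 tested and 9 lower, included Hdc (-0.48) and Clec4e (-0.73). By their mean standardised value, however, plive-Tet1 1 (0.965) was the highest of the 8 livers. The neutrophil list had a camera adjusted p of 0.0180, and the adjusted p was 0.647 with an estimated correlation. That call was lost without plive-Con 1 (adjusted p 0.139), plive-Con 2 (0.0844), plive-Tet1 3 (0.267) or plive-Tet1 4 (0.219). It was also lost with a mean FPKM of at least 2 (0.525), the highest of a range from 2.71e-05 over the settings at the preset correlation.

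Of 22 markers of liver sinusoidal endothelial cells, 21 had a lower value and 0 passed adjusted over the list alone. By mean standardised value, however, plive-Tet1 4 (0.585) lay above plive-Con 2, 3 and 4, and plive-Con 1 (1.32) was the highest. Egfl7 had a log2 fold change of -0.48, Gpr182 of -0.40 and Kdr, a receptor for vascular endothelial growth factor, of -0.44. Camera gave an adjusted p of 7.86e-07, and the adjusted p was 0.505 with an estimated correlation. Of 9 red cell and platelet genes, 4 fell adjusted over the list alone, all globins: Hba-a1, Hba-a2, Hbb-bt (-0.84) and Hbb-bs (-0.78). The other 5 did not pass, and Alas2, the erythroid heme synthesis enzyme, had 0.26. The globin pairs are near-identical copies, so the split within each pair is uncertain. The camera adjusted p of this list was 8.77e-05, and the adjusted p was 0.278 with an estimated correlation. Markers of lipid-associated and monocyte-derived macrophages had a higher value in 19 of 25, although plive-Con 2, at a mean standardised value of 0.666, lay above plive-Tet1 2, 3 and 4. Gpnmb had 0.71, Trem2 0.51 and Fabp5 0.43, and 0 passed adjusted over the list alone. Camera's adjusted p was 0.00242, and the adjusted p was 0.716 with an estimated correlation. That camera call was lost without plive-Con 3 (adjusted p 0.448), plive-Con 4 (0.0614) or plive-Tet1 1 (0.570), and with library weights in limma (0.242). Camera's adjusted p ranged from 8.11e-06 to 0.570 over the settings at the preset correlation.

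The fibrosis list had 33 of 39 members with a higher value, a median log2 fold change of 0.18 and 0 members passing adjusted over the list alone. By mean standardised value, plive-Con 2 (0.569) and plive-Con 1 (0.533) were the highest of the 8 livers, plive-Con 3 (-1.44) and plive-Con 4 (-0.795) the lowest. Mmp2 had 0.48, Tgfb2 0.52 and Col4a1, a basement membrane collagen, 0.26. By camera the adjusted p was 6.58e-05, and the adjusted p was 0.710 with an estimated correlation. The call was lost without plive-Con 3 (adjusted p 0.325, the highest of a range from 1.05e-08). Of 27 genes of the unfolded protein and integrated stress response, 23 had a higher value and 0 passed adjusted over the list alone. Hyou1, an endoplasmic reticulum chaperone, had 0.36, Eif2ak3, the kinase PERK, 0.33 and Psat1, of serine synthesis, 0.42. The mean standardised value of plive-Con 1 (0.139) nevertheless lay above that of plive-Tet1 4 (0.0923). Camera gave this list an adjusted p of 8.57e-06, and the adjusted p was 0.414 with an estimated correlation.

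All 34 tested nuclear subunits of oxidative phosphorylation had a lower value, with a median log2 fold change of -0.17 and 0 passing adjusted over the list alone. plive-Tet1 1 nevertheless had a mean standardised value (-0.0189) just above that of plive-Con 2 (-0.0310). Uqcrq had -0.37, Ndufa5 -0.42 and Ndufb3 -0.23. In camera's test the adjusted p was 3.02e-08, and the adjusted p was 0.414 with an estimated correlation. All 13 mitochondrially encoded genes also had a lower value, mt-Co3 with -1.16 (-0.55 without plive-Con 3, which measured 142 CPM) and mt-Co1 with -0.52, and 0 passed adjusted over the list alone. By their mean standardised value, however, plive-Tet1 1 (0.992) lay above plive-Con 1, 3 and 4. The camera adjusted p of these genes was 0.000704, and the adjusted p was 0.647 with an estimated correlation. The call was lost without plive-Con 2 (adjusted p 0.0877) or plive-Tet1 3 (0.137, the highest of a range from 1.40e-08), and mitochondrial genes took from 3.23% to 8.63% of the counts of a library, the most in plive-Con 2. All 25 genes of the cholesterol synthesis list had a lower value, Stard4 with -0.45 and Msmo1 with -0.40, and 0 passed adjusted over the list alone. By mean standardised value, however, plive-Con 2 (-0.637) lay below plive-Tet1 2, 3 and 4. For cholesterol synthesis camera gave an adjusted p of 1.24e-05, and the adjusted p was 0.565 with an estimated correlation. The call was lost without plive-Con 3 (adjusted p 0.0634, the highest of a range from 9.22e-09).

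Among the 8 livers, plive-Con 4 had the highest mean standardised value in the lists of fat oxidation (1.74), female-biased (1.86) and xenobiotic genes (0.722), and the lowest in the male-biased list (-1.48). Of 35 genes of fatty acid oxidation and PPARalpha targets, 32 had a lower value and 0 passed adjusted over the list alone. plive-Con 1 (-0.568) and plive-Con 2 (-0.658), however, lay below plive-Tet1 2, 3 and 4 by the list's mean standardised value. The camera adjusted p of this list was 8.56e-05. The adjusted p was 0.716 with an estimated correlation. Camera's adjusted p was 0.914 without plive-Con 4, 0.0582 without plive-Tet1 1 and 0.467 with library weights in limma, in a range from 1.05e-08 to 0.914. Acot3, an acyl-CoA thioesterase, measured 141 CPM in plive-Con 4 and between 6.87 and 10.3 CPM in the other 3 plive-Con livers, and Cyp4a10 measured 1311 CPM against 255 to 392.5 CPM. Of 8 female-biased genes, 5 fell adjusted over the list alone, among them Acot3 and Cyp2b9. Without plive-Con 4, the log2 fold changes were -0.999 instead of -3.21 for Acot3, -0.84 instead of -1.57 for Cyp2b9 and -0.35 instead of -1.20 for Cyp4a10. Camera gave the female-biased list an adjusted p of 9.49e-05, which was 0.00362 without plive-Con 4, and the adjusted p was 0.447 with an estimated correlation. Of 29 xenobiotic-metabolising enzymes and receptors, 3 fell adjusted over the list alone, among them Cyp2b9 and Nr1i3, the nuclear receptor CAR. By mean standardised value, however, plive-Tet1 4 (0.314) lay above plive-Con 1 and 2. Camera gave the xenobiotic list an adjusted p of 0.000151, which was 0.00771 without plive-Con 4. The adjusted p was 0.498 with an estimated correlation. Of 23 male-biased genes, 2 rose adjusted over the list alone, Cyp4a12a and Cyp4a12b, while C6 had 0.58. The list's camera direction was higher (adjusted p 0.00439; adjusted p 0.716 with an estimated correlation), its median log2 fold change was 0.01 and its mean, of the opposite sign, -0.10. Without plive-Con 4 the direction turned to lower (adjusted p 0.791). The call was lost without plive-Tet1 3 (0.0598) and with library weights in limma (0.779), in a range of camera's adjusted p from 1.50e-08 to 0.791.

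Of 20 tested circadian clock genes, 1 rose and 5 fell adjusted over the list alone. Arntl, the clock activator BMAL1, had a log2 fold change of 1.13, and Per3 and Per2, repressors of the clock, had -1.14 and -0.70. The others that fell were Dbp, Usp2 and Tef. plive-Tet1 3 and 4 nevertheless lay above plive-Con 1 and 2 by the list's mean standardised value. Camera's adjusted p was 0.00358, and the adjusted p was 0.414 with an estimated correlation. The call was lost without plive-Con 3 (adjusted p 0.0634) or plive-Con 4 (0.0642, the highest of a range from 2.42e-05). Of 31 hepatocyte secreted and identity genes, 23 had a lower value, Nr1i3 with -0.64 and Apoc3 with -0.35, and 0 passed adjusted over the list alone. By mean standardised value, however, plive-Con 2 (-0.671) was the lowest of the 8 livers. The hepatocyte list had a camera adjusted p of 0.00727, and the adjusted p was 0.647 with an estimated correlation. Its call was lost without plive-Con 3, plive-Con 4 or plive-Tet1 1 (adjusted p 0.217, 0.0743 and 0.0703). It was also lost by limma on quantile-normalised log2(FPKM + 0.5) (0.843), the highest of a range from 6.42e-05 over the settings at the preset correlation.

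**Figure D3:**
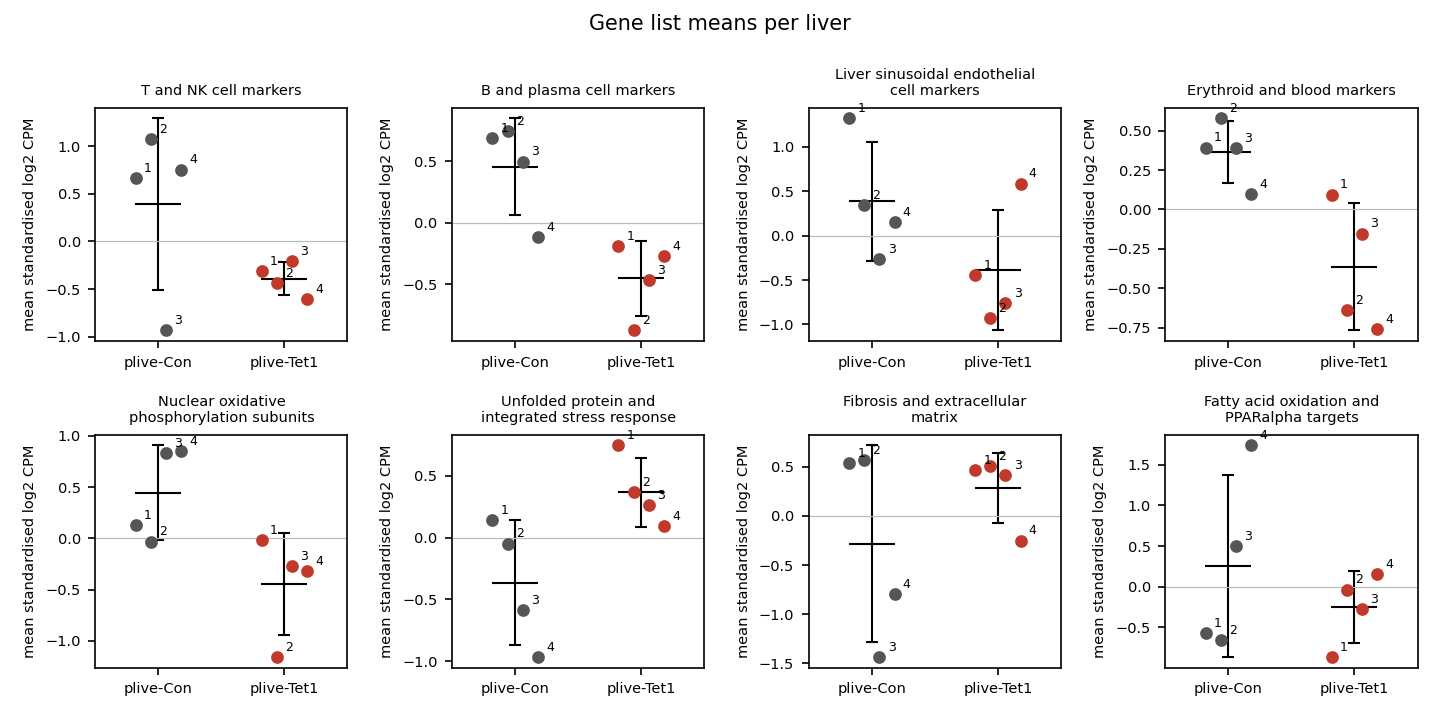
Mean standardised log2 CPM of the members of 8 gene lists in each liver (linear axes, no unit). Points are single livers with their replicate number, and the bar and whiskers give the mean and SD (n = 4); plive-Con 4 lay at 1.74 for fatty acid oxidation and PPARalpha targets, where the next library lay at 0.4996.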

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

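Except for the splits of the libraries, all tests in this part were chosen after the results had been seen. Across the 35 splits of the 8 libraries into 4 and 4, chance cannot be excluded for the genes at an unadjusted p under 0.05 or for the called lists. The real split gave 0 genes past the threshold, which any split must reach, so that count tests nothing. The highest number past the threshold in another split was 5. The real split gave 591 genes at an unadjusted p under 0.05, which 19 of 35 splits reached, and the highest other split gave 1977. That split, of plive-Con 1, plive-Con 2, plive-Tet1 1 and plive-Tet1 4 against the others, gave 0 genes past the threshold. The 18 lists called by camera were reached in 10 of 35 splits, and the highest other split called 24.

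A library far from the other 3 of its group was found in 19 of 336 groups of values tested, where chance, at about 1 in 20, gives 16.8, and in 9 of the 19 that library was plive-Con 4. There Acot3 measured 141 CPM, Cyp4a10 1311 CPM, G0s2 137 CPM and Acot4 239 CPM, all above the other plive-Con livers. Ddc (23.4 CPM), Scd1 (41.2 CPM) and Dnmt3b (0.956 CPM) lay below them, and the mean standardised values of the female-biased list (1.86) and the ferroptosis and iron list (0.601) lay above. Other livers apart from their group were plive-Tet1 1 for Hba-a1 (56.1 CPM) and Retnlg (1.24 CPM), and plive-Tet1 2 for Smim4 (1.904 CPM). plive-Con 1 was apart for Cd79a (4.00 CPM) and Adgre1 (67.3 CPM), and plive-Con 3 for Ihh (5.41 CPM) and the fetal liver and tumour list (-0.945). plive-Tet1 4 was apart for Scd1 (352 CPM), Dnmt3b (1.63 CPM) and the fibrosis list (-0.252).

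The profile of plive-Con 4 argues against a female animal, since its summed level of 4 Y-linked genes was 92.4% of the median of the other 7 libraries. It also argues against sequencing depth, since its 17.4 M counts lay inside the range of the others, 15.9 to 19.9 M. A longer fast or another state of fat oxidation at killing may be behind it, but cannot be told apart. The fatty acid oxidation and PPARalpha list was 1.24 standardised units above the next library, yet 3 of the genes that set plive-Con 4 apart are members of that list, so this value decides nothing. The fasting time of single animals is not given in the sources used here, and the design names no group difference that could set 1 control liver apart.

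Clock activators (Arntl, Clock and Npas2) had a mean log2 difference of 0.83 in plive-Tet1 livers, and 11 other clock genes one of -0.54. These 11, called outputs for short, were Per1, Per2, Per3, Nr1d1, Nr1d2, Dbp, Tef, Hlf, Ciart, Bhlhe41 and Usp2. They include repressors of the clock such as Per2 and Per3. Another clock phase at killing could produce opposite shifts, but the exact permutation p of outputs minus activators was 0.0571, and the hour of killing is not given in the sources used here. Without plive-Con 4 the difference was -1.02 on the log2 scale instead of -1.37, with overlapping groups, so that library alone cannot be told apart as its source. An effect of the plasmid stays open and untested.

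Blood, lymphoid and endothelial markers had lower values in plive-Tet1 livers. None of these lists was called with an estimated correlation, and plive-Con 3 had the lowest T and NK value of all 8 livers. For endothelial markers, plive-Tet1 4 lay above plive-Con 2, 3 and 4. A lower share of all cells other than hepatocytes may lower every such list alike, whereas the mean log2 difference was -0.49 for T and NK, -0.01 for stellate, 0.06 for bile duct and 0.21 for lipid-associated macrophage markers. Yet the exact permutation p was 0.0857 for T and NK against macrophage markers. It was 0.2 for the spread of the difference over 9 cell type lists. The hepatocyte list did not rise, since 23 of its 31 genes were lower, without a call at an estimated correlation. CPM is relative to the library's total, so that list could hardly rise if hepatocyte RNA made up most of it. Its values therefore decide nothing here. A lower share of cells other than hepatocytes therefore cannot be told apart at this sample size. Less residual blood could lower globins, and the other 5 blood genes, at a median of 3.06 CPM too near the floor to decide, had a difference of -0.06 against -0.97 for globins (exact permutation p 0.0571); an effect of the plasmid stays open.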

How the results depend on the processing

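Settings named as added in the account of the processing were chosen after seeing the data. With all 8 libraries or with any library left out, 0 genes were higher and 0 lower in every fit except edgeR without a filter and DESeq2. Without a filter edgeR called 33 genes higher and 99 lower, and 1538 genes had an unadjusted p under 0.05. That fit's prior degrees of freedom were 799, against 6.87 with filterByExpr, so a gene's own spread had little weight; with more than 20 counts over all libraries they were 8.04 and 0 genes were called. DESeq2 called 5 higher and 6 lower; the cause was not tested. Over all other fits the smallest adjusted p lay between 0.0604 (edgeR with library totals) and 0.639 (without plive-Con 1). The 591 genes at an unadjusted p under 0.05 became 342 with a mean FPKM of at least 2, where fewer genes were tested (8844), and 1187 with library weights in limma; the cause of the latter was not tested. Leaving out 1 library gave from 293 (without plive-Tet1 2) to 725 such genes. The 18 lists called by camera became 0 with an estimated correlation and 0 with fry, which allow for correlated members, and 0 with the exact permutation test, whose smallest possible p of 0.0286 can hardly pass the adjustment; camera at the preset correlation called from 15 to 22 in the other settings. Of the 18 lists, 9 stayed called in every setting at the preset correlation that tested them, which was 20 for the T and NK and the B and plasma cell lists and 21 for the others; with a mean FPKM of at least 2 those lists had too few members. The male-biased list turned to lower values without plive-Con 4, with an adjusted p of 0.791, and with 1 library left out its adjusted p ranged from 1.50e-08 to 0.791. The Tet1 ratio of mean CPM stayed above 1 in every setting that gave one, from 1.14 without plive-Con 1 to 1.91 without plive-Con 2, with no exact p under 0.05. Among named genes, 30 of 3035 values changed sign with no call in either fit, in 9 genes, and 0 changed sign with a call. With the replicate number as a block, 0 genes were higher, 0 lower, 616 had an unadjusted p under 0.05 and 20 lists were called. No strong shared deviation of same-numbered libraries was seen, although a weak pairing is not excluded and what the numbers mark is not stated. The correlations of same-numbered deviations were 0.035, -0.032, 0.119 and -0.0026, and 1 of 4 plive-Tet1 libraries correlated best with its own number. Tet1 had at most 12 counts in a library, which limits how closely its ratio can be estimated. Pooled ratios above 2.62 nevertheless lay outside the interval of counting error.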

Other observations

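All tests in this part were planned before the data were examined. Of 4 lists with too few tested members for camera, the germline genes silenced by promoter methylation bear on the plasmid's target, since loss of methylation can switch such genes on. Over the 21 germline genes found in the table, 224 counts were collected in the plive-Con livers and 240 in the plive-Tet1 livers. This is 3.24 and 3.21 CPM of the pooled counts. Only 13 of the 21 genes had a count in any library, and 1 gene, Brdt, passed the expression filter. Brdt had a mean of 1.97 CPM with plive-Con and 1.87 CPM with plive-Tet1, so the pooled values mostly reflect that gene. Imprinted genes, of which 24 were tested, had a median log2 fold change of 0.10 and 0 members passing adjusted over the list alone (camera adjusted p 0.606). Of the pooled counts of the plive-Con and plive-Tet1 livers, genes of the sex chromosomes took 49.8 and 49.2 CPM, pancreatic acinar markers 14.4 and 14.6 CPM and adipocyte markers 171 and 140 CPM, with no test of the difference.

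Bile acid synthesis and transport held 1 gene that fell adjusted over the list alone, Abcg5 (adjusted p 0.0250 from edgeR over the list), while its partner Abcg8 had a log2 fold change of -0.46 and did not pass. In the fetal liver and tumour list, Golm1 rose and Tff3, a trefoil peptide, fell adjusted over the list alone, with log2 fold changes of 0.68 and -0.87. Resident Kupffer cell markers, 21 tested, had 0 members passing adjusted over the list alone, and Cd163, a scavenger receptor, had -1.27. Of 37 interferon response genes 28 had a lower value, Igtp with -0.44, and the camera adjusted p was 0.0516. Of 24 p53 targets 18 had a higher value, Zmat3 with 0.37 and Cdkn1a with 0.57, and the camera adjusted p was 0.0573.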
